A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

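RNA sequencing was done on 2 groups of yeast culture with 2 libraries each, which gave 4 libraries. The hybrid group was a diploid made from the strains BY4741 and RM11-1alpha, and the co-culture group was a mixture of the haploid strains BY4741 and RM11-1a. Per the labels' protocols, 4 technical replicate cultures of each kind were started at an OD600 of 0.1 and harvested at an OD600 of 1.0, at 30 °C and 250 rpm. Per the same protocols, RNA was extracted with hot acid phenol. Libraries were made from 5 µg of total RNA with polyA selection, fragmentation at 94 °C for 8 min and random priming. Each product was split for 2 separate PCR reactions with different reagents, of 12 cycles each. The labels do not say which culture or which PCR reaction a library number stands for.

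Per the file headers, each deposited file holds read counts on the SNP sites of 4442 orthologous gene pairs, with the BY reads and the RM reads of a pair in separate columns. The values are whole numbers and were taken as the authors' raw read counts, with no scaling. Per the submitters' processing notes, the tools were CASAVA 1.8.2 and Bowtie, whose version and settings were not given. The genome build, the SNP set and the handling of a read that covers more than 1 SNP are not given in the sources used here. Symbols, chromosomes, neighbouring genes and GC content came from the R64 reference annotation, matched by systematic name. Of the 4442 names, 4325 matched and 117 did not, and the latter are printed by their systematic name only. GC content was known for 97.4% of the genes. The annotation placed 89 genes in overlap with another gene, and values of such genes are uncertain because the reads were counted without a stated strand.

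The total of a gene in a library was the sum of its BY and RM reads. Counting floors were set at 3 reads of a library, and shares of reads were given with 95% Wilson intervals. The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with TMM scaling, filterByExpr with its minimum count of 10, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Hybrid and co-culture totals were compared in a fit of the 4 libraries with 2 residual degrees of freedom. Allele ratios were compared in a fit of the 8 allele columns with library as a block and 2 residual degrees of freedom, in which each allele column was scaled by its own total. That scaling removes the mixing ratio of the strains. From it came the BY over RM ratio in the co-culture (the parental difference), the ratio in the hybrid (the cis difference, since both alleles share a nucleus) and the first minus the second (the trans difference). Regulatory classes combined the 3 calls. Inheritance classes came from a fit of hybrid totals and of the BY and RM columns of the co-culture, with 3 residual degrees of freedom. These 2 sets of comparisons use the same libraries more than once, so overlaps were set against the overlap of independent lists and against 20 simulated data sets without differences.

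Before the data were examined, the groups, tests, class rules, gene lists, most alternatives and the rule for naming genes were fixed. Of 33 gene lists, 29 with at least 3 tested members in each fit were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The calls of their members were also counted when adjusted over the list alone. The named genes of a comparison were the 8 largest rises and the 8 largest falls among genes past the adjusted p of 0.05, with a mean of at least 50 reads per library, and the same direction in each library. To these were added up to 4 members per list with the smallest p and the strain marker genes. Where a group had 0 reads, the ratio was given as a lower bound at 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% counting interval. Plots of log2 ratios use a pseudocount of 0.5 reads.

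Alternatives were DESeq2 1.42.0, RLE scaling, column totals only, library totals shared by both alleles, no filter, a mean of at least 50 reads per column, a log2 change of at least 0.32, a replicate block, no library block, exact binomial tests, the mid-parent, fry, camera with an estimated correlation, and each library left out in turn. For the sizes of cis and trans differences, the alternatives were the use of the same libraries, the exchange of the hybrid libraries and a minimum of 100 reads per allele column. Fits without chromosome XIII, and sizes without the strain marker genes or without genes at 8-fold or more in both cultures, were chosen after seeing the data. Intervals of medians and correlations over genes came from 2000 bootstrap draws of genes, which treat genes as independent. Simulated data showed what the tests recover: a 1.5-fold difference was called in 89.6% of altered genes for totals, 65.7% for the co-culture ratio, 77.6% for the hybrid ratio and 50.7% for their difference. For a 2-fold difference these shares were 100.0%, 97.0%, 95.5% and 79.1%. The altered genes all had an expected count above a minimum, and every simulated gene had a dispersion of 0.002. The shares therefore do not hold for genes with few reads or with a larger spread. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the counts and drew the plots. A gene that the naming rule picked was left out of the text because it is withheld for evaluation. No library was left out of the main results, and genes below the filter were left out of the tests only.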

Results

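Messenger RNA was measured in yeast cells in which the genomes of a laboratory strain and a vineyard strain either shared a nucleus or shared a flask. The hybrid was an a/alpha diploid from a cross of BY4741, a laboratory strain, with RM11-1alpha, from a line derived from a vineyard isolate. The co-culture was a mixture of BY4741 and RM11-1a, both haploid and of mating type a. The series title names how expression levels are inherited and how selection constrains cis and trans changes. Each group had 2 libraries, called replicates 1 and 2, and each gene pair had BY reads and RM reads counted on SNP sites. Total counts were 2809121 and 4183129 in hybrid replicates 1 and 2, and 2692044 and 3143817 in co-culture replicates 1 and 2. The median gene had 213, 324, 219 and 257 reads in the same order. Levels are given in CPM, read counts scaled to the library. A count of 0 allows up to 1.07, 0.72, 1.11 and 0.95 CPM (3 reads of the total). BY reads made up 49.62% of the reads in hybrid replicate 1 (95% Wilson interval 49.56 to 49.68), 49.57% in hybrid replicate 2 (49.52 to 49.62), 49.53% in co-culture replicate 1 (49.47 to 49.59) and 49.51% in co-culture replicate 2 (49.46 to 49.57). Intervals and floors cover counting error only. The labels call the cultures technical replicates, so all p-values measure the spread between technical replicate samples. Since the labels do not say which culture or PCR reaction a library is, that spread may leave out differences between cultures. Errors of CPM are SD and errors of log2 changes are SE, with n = 2 libraries per group throughout. Named genes had the same direction in each library. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

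Strain marker genes had reads from 1 allele alone in some cultures. MET17 (YLR303W), a methionine synthesis gene that is deleted in BY4741, had 0 BY reads and 533 RM reads in the co-culture, at least 185-fold higher in RM. In the hybrid it had 1 BY read and 507 RM reads, a ratio of 499 (95% counting interval 89.2 to 1.98e+04). Its reads are uncertain because it overlaps YLR302C. LYS2 (YBR115C), a lysine synthesis gene, had 0 RM reads and 2224 BY reads in the hybrid, at least 752-fold higher in BY. In the co-culture its log2 BY over RM was 0.04 ± 0.06 (adjusted p = 0.606), so the RM copy was without reads only in the hybrid. The RM parents named in the labels also differ, RM11-1alpha in the hybrid and RM11-1a in the co-culture. AFB1 (YLR040C), a gene expressed in alpha cells, fell by 1.97 ± 0.24 on the log2 scale in the hybrid against the co-culture (adjusted p = 3.44e-08). SAG1 (YJR004C), the alpha-agglutinin gene, did not pass (0.18 ± 0.24, adjusted p = 0.614). Both are the tested members of an alpha-specific list too short for a list test, and were named after their values were seen.

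Hybrid totals were compared with co-culture totals to ask which genes change level when both genomes share a diploid nucleus. The groups also differed in mating type and in the named RM parent, RM11-1alpha in the hybrid and RM11-1a in the co-culture. A change in totals therefore cannot be credited to the shared nucleus alone. Genes that let haploid cells mate were far lower in the hybrid than in the co-culture. STE2 (YFL026W), which encodes the alpha-factor receptor, stood at 32.8 ± 0.7 CPM in the hybrid and 4140.0 ± 15.7 in the co-culture. Its log2 change was −6.98 ± 0.08 (adjusted p = 1.23e-38). MFA1 (YDR461W), the a-factor precursor gene, went from 313.4 ± 16.1 in the co-culture to 2.0 ± 1.3 in the hybrid, a log2 change of −7.16 ± 0.17. BAR1 (YIL015W), whose product degrades alpha-factor, changed by −6.40 ± 0.11 and STE6 (YKL209C), the a-factor exporter gene, by −4.94 ± 0.07. All 5 measured a-specific genes fell, with a median log2 change of −6.40 and a camera adjusted p of 1.09e-122 (adjusted p = 0.19 with an estimated correlation).

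The signalling genes that both haploid mating types use fell as well. STE18 (YJR086W), the G-protein gamma subunit gene, had 1 read in the hybrid and 420 in the co-culture, a ratio of 495 (95% counting interval 88.3 to 1.96e+04). GPA1 (YHR005C), the alpha subunit gene, changed by −5.30 ± 0.12, and FUS3 (YBL016W), the mating kinase gene, by −6.47 ± 0.19. RME1 (YGR044C), which represses meiosis in haploids, changed by −4.40 ± 0.27. All 9 haploid-specific genes fell, and their median of −3.05 was the same with STE18 at its count ratio (camera adjusted p = 5.93e-72, and adjusted p = 0.195 with an estimated correlation). Of 13 genes of the pheromone response, 7 fell and 0 rose, with a median of −0.61 also when KAR4 (YCL055W) was set at its bound. The list had a camera adjusted p of 4.76e-10 (adjusted p = 0.195 with an estimated correlation). Among them were SST2 (YLR452C), which ends the signal, at −2.75 ± 0.07, and PRM5 (YIL117C), a pheromone-induced membrane protein gene, at −3.69 ± 0.18. KAR4, a karyogamy regulator gene, had 0 reads in the hybrid and 66 in the co-culture, at least 25.9-fold lower.

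**Figure D1:**
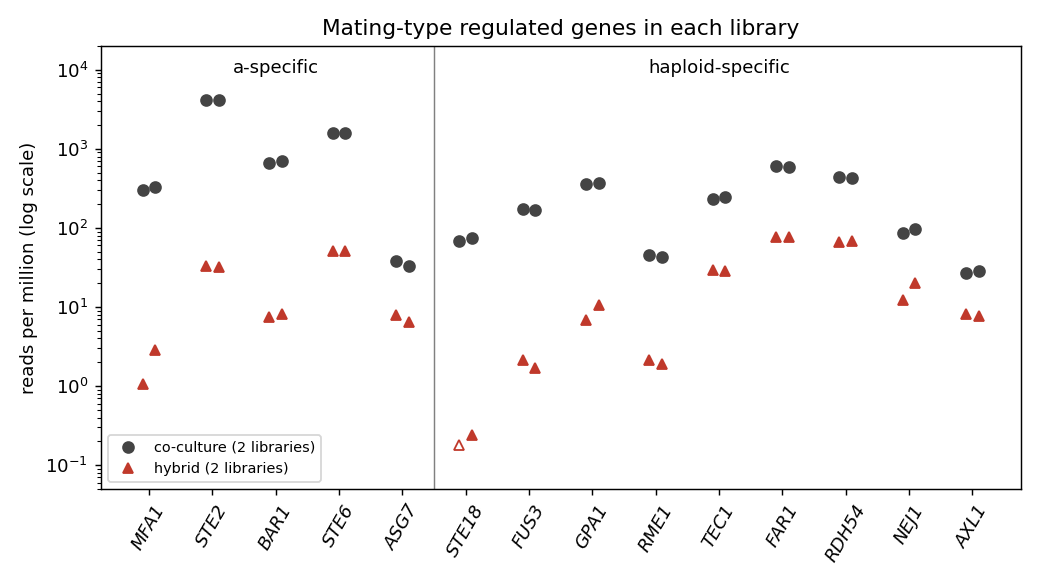
CPM on a log axis for a-specific and haploid-specific genes in each of the 4 libraries, where an open symbol marks 0 reads, drawn at 0.5 reads. All 5 a-specific and all 9 haploid-specific genes lie lower in both hybrid libraries than in both co-culture libraries.

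Most purine genes, and some leucine and branched-chain genes, were also lower in the hybrid. LEU1 (YGL009C), a leucine synthesis gene, went from 1781.0 ± 6.4 CPM in the co-culture to 402.4 ± 11.7 in the hybrid, a log2 change of −2.15 ± 0.06 (adjusted p = 2.57e-27). OAC1 (YKL120W), a mitochondrial carrier gene of the same pathway, changed by −1.99 ± 0.06 and BAT1 (YHR208W), a branched-chain transaminase gene, by −1.39 ± 0.06. Of 11 leucine and branched-chain genes 6 fell and 1 rose, with a median of −0.30 and a camera adjusted p of 9.64e-10 (adjusted p = 0.245 with an estimated correlation). Of 9 purine genes 7 fell and 0 rose, with a median of −0.31 and a camera adjusted p of 0.000139 (adjusted p = 0.245 with an estimated correlation). ADE17 (YMR120C) changed by −1.41 ± 0.08 and ADE1 (YAR015W) by −0.94 ± 0.07, and both encode enzymes of the pathway.

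Most genes of trehalose, glycogen and stress fell, and so did 9 of 17 heat shock genes. HSP30 (YCR021C), a membrane heat shock gene, changed by −3.02 ± 0.20, HSP26 (YBR072W), a small chaperone gene, by −2.39 ± 0.16 and HSP12 (YFL014W), a membrane-stabilising stress gene, by −2.42 ± 0.19. Of 17 heat shock and chaperone genes 9 fell and 3 rose, with a median of −0.41 and a camera adjusted p of 0.00264 (adjusted p = 0.245 with an estimated correlation). Of 11 genes of trehalose, glycogen and stress 8 fell and 0 rose, with a median of −0.39 and a camera adjusted p of 0.00264 (adjusted p = 0.245 with an estimated correlation). Of 7 phosphate genes 4 fell and 0 rose, with a median of −0.47 and a camera adjusted p of 0.0304 (adjusted p = 0.394 with an estimated correlation). Without co-culture replicate 1 the adjusted p of the phosphate list was 0.0509, and over its 7 alternatives it lay between 0.00325 and 0.394. SPL2 (YHR136C), a regulator of phosphate uptake, changed by −1.40 ± 0.17.

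Most ribosome biogenesis genes rose in the hybrid. Of 50 ribosome biogenesis genes 45 rose and 0 fell, with a median of 0.43 and a camera adjusted p of 2.71e-14 (adjusted p = 0.245 with an estimated correlation). NOP4 (YPL043W), a nucleolar assembly gene, rose by 0.56 ± 0.06 and RRP5 (YMR229C), a processing factor gene on chromosome XIII, by 0.66 ± 0.06. With the genes of chromosome XIII left out, 41 of 45 rose. Of 42 mitochondrial ribosomal protein genes 21 rose and 1 fell, with a median of 0.30 and a camera adjusted p of 0.000666 (adjusted p = 0.245 with an estimated correlation). MRP51 (YPL118W), of the small mitochondrial subunit, rose by 0.56 ± 0.09. Of 70 cytosolic ribosomal protein genes 25 rose and 4 fell, with a median of 0.18 and a camera adjusted p of 0.0162 (adjusted p = 0.245 with an estimated correlation).

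Membrane sterol genes and daughter cell genes moved in both directions. Of 18 ergosterol genes 9 rose and 3 fell, with a median of 0.18 and a camera adjusted p of 0.0318 (adjusted p = 0.394 with an estimated correlation). Without co-culture replicate 2 the adjusted p was 0.0693. The list had 5 members on chromosome XIII, among them ERG6 (YML008C), a sterol methyltransferase gene, which rose by 0.46 ± 0.06. Without that chromosome 5 rose and 2 fell of 13, with an adjusted p of 0.527, and over the 7 alternatives that keep all chromosomes the adjusted p lay between 0.00597 and 0.394. Of 12 daughter cell separation genes 6 fell and 2 rose, with a median of −0.24 and a camera adjusted p of 0.0179 (adjusted p = 0.394 with an estimated correlation). AMN1 (YBR158W), whose product delays separation of daughter cells, fell by 1.65 ± 0.06, and PRY3 (YJL078C), a cell wall gene, rose by 0.79 ± 0.06. DSE1 (YER124C), a cell wall gene of daughter cells, and CTS1 (YLR286C), the endochitinase gene, fell by 0.76 ± 0.07 and by 0.48 ± 0.06. Against the mean of the parents' log2 levels, each scaled separately, both were instead higher in the hybrid, by 0.84 and 0.58. DSE1 stood at 176.5 CPM in the hybrid, 565.7 in BY and 16.8 in RM on that scaling, and CTS1 at 2199.4, 5624.4 and 385.2.

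The largest rises in the hybrid were smaller than the falls. RPS18B (YML026C) rose by 1.38 ± 0.21, RPS16A (YMR143W) by 1.32 ± 0.17, RPS26B (YER131W) by 1.31 ± 0.17 and RPL26B (YGR034W) by 1.01 ± 0.21. These ribosomal protein genes have near-identical paralogs, which makes their read assignment uncertain, and RPS18B and RPS16A lie on chromosome XIII. CYC3 (YAL039C), which attaches heme to cytochrome c, rose by 1.11 ± 0.18, MMP1 (YLL061W), the S-methylmethionine permease gene, by 1.04 ± 0.07 and ZRT1 (YGL255W), the high-affinity zinc transporter gene, by 0.95 ± 0.06. In all, 1544 of 4327 genes tested (35.7%) differed between hybrid and co-culture totals, 769 higher and 775 lower in the hybrid. At least 2-fold were 8 higher and 112 lower. DESeq2 called 809, and 1020 also passed a fold change minimum. On chromosome XIII, 167 of 341 genes were higher and 17 lower. On the other chromosomes 602 were higher and 758 lower, and in a fit without chromosome XIII, which rescales the libraries, 720 were higher and 633 lower. The split was 685 higher and 851 lower with column totals only and 916 and 691 against the mean of the parents' log2 levels. Adjusted over the list alone, the counts of called lists were the same except for mitochondrial ribosomal proteins (24 higher) and heat shock (4 higher). Of 29 lists, 13 passed camera (15 at an unadjusted p), and with an estimated correlation 0 passed, while 5 did at an unadjusted p and fry called 26.

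The parental difference, BY over RM in the co-culture, asked which genes the strains express differently in the same medium. Most genes for the release of daughter cells were higher in BY. The log2 BY over RM of DSE1 was 5.05 ± 0.12, of DSE2 (YHR143W), another daughter-specific cell wall gene, 4.49 ± 0.07, of CTS1 3.88 ± 0.04 and of SCW11 (YGL028C), a glucanase gene, 3.39 ± 0.09. Of 12 daughter cell separation genes 10 were higher in BY and 0 in RM, with a median of 1.03 and a camera adjusted p of 7.67e-17 (adjusted p = 0.18 with an estimated correlation).

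Oxidative phosphorylation genes were higher in RM. CYC1 (YJR048W), the cytochrome c gene, had a log2 BY over RM of −3.28 ± 0.09 (adjusted p = 3.04e-255), RIP1 (YEL024W), the Rieske protein gene, −2.41 ± 0.07 and CYT1 (YOR065W), the cytochrome c1 gene, −2.05 ± 0.06. All 23 measured oxidative phosphorylation genes were higher in RM, with a median of −1.12 and a camera adjusted p of 1.79e-25 (adjusted p = 0.18 with an estimated correlation). Of 42 mitochondrial ribosomal protein genes 29 were higher in RM and 0 in BY, with a median of −0.46 and a camera adjusted p of 0.000503 (adjusted p = 0.319 with an estimated correlation). HAP1 (YLR256W), which encodes a heme-responsive activator of respiration genes, was itself higher in BY, by 1.08 ± 0.06. Of 10 genes of the HAP1, heme and oxygen list 3 were higher in BY and 5 in RM, with a median of −0.46 and a camera adjusted p of 0.0251 (adjusted p = 0.341 with an estimated correlation). That call ended without co-culture replicate 2 (0.0568) and without chromosome XIII (0.153), and over the 7 alternatives that keep all chromosomes the adjusted p lay between 8.82e-05 and 0.341.

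Most ergosterol and iron genes were also higher in RM. ERG11 (YHR007C), the sterol demethylase gene, had a log2 BY over RM of −1.48 ± 0.04 and HMG1 (YML075C), the HMG-CoA reductase gene on chromosome XIII, −1.83 ± 0.05. Of 18 ergosterol genes 15 were higher in RM and 2 in BY, with a median of −0.72 and a camera adjusted p of 2.78e-12 (adjusted p = 0.18 with an estimated correlation). FTR1 (YER145C), the iron permease gene, was at −1.10 ± 0.05, FRE2 (YKL220C), a metalloreductase gene, at −2.12 ± 0.13 and HMX1 (YLR205C), the heme oxygenase gene, at −3.10 ± 0.17. Of 12 iron uptake genes 10 were higher in RM and 0 in BY, with a median of −0.97 and a camera adjusted p of 7.46e-07 (adjusted p = 0.354 with an estimated correlation).

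Most phosphate and heat shock genes, and some proteasome genes, were higher in BY. VTC3 (YPL019C), a polyphosphate synthesis gene, had a log2 BY over RM of 1.88 ± 0.04, SPL2 2.58 ± 0.23 and PHO84 (YML123C), the phosphate transporter gene, 1.62 ± 0.04, although PHO84 overlaps a non-coding RNA. Of 7 phosphate genes 6 were higher in BY and 1 in RM, with a median of 1.23 and a camera adjusted p of 2.14e-07 (adjusted p = 0.341 with an estimated correlation). HSP104 (YLL026W), the disaggregase gene, was higher in BY by 1.21 ± 0.07 and SIS1 (YNL007C), a co-chaperone gene, by 0.80 ± 0.06, while HSP60 (YLR259C), the mitochondrial chaperonin gene, was at −0.48 ± 0.03. Of 17 heat shock and chaperone genes 11 were higher in BY and 1 in RM, with a median of 0.48 and a camera adjusted p of 0.00127 (adjusted p = 0.341 with an estimated correlation). RPN4 (YDL020C), which encodes the transcription factor of proteasome genes, was higher in BY by 2.89 ± 0.11 and PRE7 (YBL041W), a core subunit gene, by 1.72 ± 0.07. Of 26 proteasome genes 8 were higher in BY and 1 in RM, with a median of 0.07 and a camera adjusted p of 0.0286 (adjusted p = 0.341 with an estimated correlation).

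Leucine, pheromone and cytosolic ribosomal protein genes passed as lists only with all libraries or most of them. Of 11 leucine and branched-chain genes 5 were higher in BY and 2 in RM, with a median of 0.09 and a camera adjusted p of 0.0412 (adjusted p = 0.341 with an estimated correlation). BAT2 (YJR148W), the cytosolic transaminase gene, was higher in BY by 2.06 ± 0.08. The leucine call ended without hybrid replicate 1 (0.0517), co-culture replicate 1 (0.0697), co-culture replicate 2 (0.0568) or chromosome XIII (0.107), and over the 7 alternatives that keep all chromosomes its adjusted p lay between 0.00628 and 0.341. Of 13 pheromone response genes 5 were higher in BY and 0 in RM, with a median of 0.34 and a camera adjusted p of 0.0451 (adjusted p = 0.341 with an estimated correlation). FIG2 (YCR089W), a mating cell wall gene, was higher in BY by 2.56 ± 0.20. The pheromone call ended without hybrid replicate 1 (0.163), hybrid replicate 2 (0.163) or co-culture replicate 2 (0.0577), within a range of 0.00759 to 0.341. Of 70 cytosolic ribosomal protein genes 33 were higher in RM and 18 in BY, with a camera adjusted p of 0.0451 towards RM (adjusted p = 0.341 with an estimated correlation). Their median was −0.10 and their mean 0.20, of opposite sign. That call ended without hybrid replicate 1 (0.172), hybrid replicate 2 (0.17) or co-culture replicate 2 (0.0568), within a range of 0.00409 to 0.341. RPL9B (YNL067W), of the large subunit, was higher in RM at −1.01 ± 0.05.

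Several genes had reads from nearly 1 strain alone. A bias in reads assigned to an allele could also give such ratios, and this was not tested for these genes. DNF2 (YDR093W), a lipid flippase gene, had 435 BY reads and 0 RM reads in the co-culture, at least 139-fold higher in BY (adjusted p = 0.0573 by DESeq2). IME1 (YJR094C), the master activator gene of meiosis, had 213 BY reads and 2 RM reads, a ratio of 102 (95% counting interval 28 to 851). NDJ1 (YOL104C), a meiotic telomere gene, was higher in BY by 5.06 ± 0.21 and YBT1 (YLL048C), a vacuolar transporter gene, by 6.17 ± 0.12. In RM, PTK1 (YKL198C), a kinase gene of polyamine transport, had 436 reads against 2 BY reads, a ratio of 227 (62.4 to 1.88e+03). CTR3 (YLR411W), a copper transporter gene, was at −4.26 ± 0.17 and CWP1 (YKL096W), a cell wall mannoprotein gene, at −3.35 ± 0.04. In all, 1878 of 4269 genes tested (44.0%) differed between the parents, 881 higher in BY and 997 higher in RM, and at least 2-fold 253 and 141. With column totals only the split was 1139 and 755. Without co-culture replicate 2, 1178 genes differed, and by DESeq2 834. Adjusted over the list alone, the counts of called lists were the same except for cytosolic ribosomal proteins (21 higher in BY) and mitochondrial ribosomal proteins (31 higher in RM). Of 29 lists, 12 passed camera (13 at an unadjusted p), and with an estimated correlation 0 passed, while 4 did at an unadjusted p and fry called 23.

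The ratio of BY to RM alleles in the hybrid asked which of these differences are carried by the gene copy itself. Regulators and enzymes with an allele difference in the hybrid lay in many pathways. RPN4 had a log2 BY over RM of 3.16 ± 0.11 in the hybrid, and ARG4 (YHR018C), an arginine synthesis gene, 2.70 ± 0.14. UTP22 (YGR090W), a ribosome assembly gene, was at 2.24 ± 0.08, while BRX1 (YOL077C), another, was at −1.59 ± 0.06. ATP1 (YBL099W), the ATP synthase alpha subunit gene, was at −0.89 ± 0.03, IDI1 (YPL117C), an isoprenoid synthesis gene, at 1.18 ± 0.06 and HAP1 at 0.51 ± 0.06. CTR3 stood at −4.73 ± 0.19, SMA2 (YML066C), a spore membrane gene on chromosome XIII, at −2.99 ± 0.19 and YBT1 at 5.95 ± 0.10. RSC3 (YDR303C), a chromatin remodeller gene, had 549 BY reads and 1 RM read, a ratio of 557 (95% counting interval 99.6 to 2.21e+04). PTK1 had 0 BY reads and 630 RM reads, at least 207-fold higher in RM. A bias in reads assigned to an allele could also give such ratios, alike in both cultures. It would be counted as a cis difference, and it was not tested for these genes. RPL14B (YHL001W), a ribosomal protein gene with a paralog and so of uncertain read assignment, was at 4.86 ± 0.07.

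Respiration, daughter cell and ergosterol genes, which separated the parents, had medians nearer 0 between the alleles of the hybrid. Of 23 oxidative phosphorylation genes 5 were higher from BY and 5 from RM, with a median of 0.03. Of 12 daughter cell separation genes 1 was higher from BY and 4 from RM, with a median of −0.13, and of 18 ergosterol genes 7 and 8 were, with a median of −0.01. Among other lists that separated the parents, 4 genes were higher from BY and 2 from RM of 10 in the HAP1, heme and oxygen list (median 0.29, fry adjusted p = 0.0417), and 3 and 0 of 13 were in the pheromone response (fry adjusted p = 0.0496). By fry, which asks whether the genes of a list move 1 way on balance, the adjusted p was 0.0101 for oxidative phosphorylation, 0.0417 for ergosterol, 0.0101 for cytosolic and 0.013 for mitochondrial ribosomal proteins, 0.0101 for pyrimidine and 0.0417 for lysine. Adjusted over the list alone these counts were the same. The lysine list holds LYS2, which had 0 RM reads in the hybrid. In a fit without chromosome XIII, 6 ergosterol genes were higher from BY and 3 from RM of 13. Their median was 0.10 (camera adjusted p = 0.488). In the HAP1, heme and oxygen list 4 genes were then higher from BY and 0 from RM of 8. Their median was 0.45 (camera adjusted p = 0.0827). The oxidative phosphorylation and daughter cell medians were 0.01 and −0.15 in that fit. With all chromosomes, 0 of 29 lists passed camera, 0 did at an unadjusted p and 0 with an estimated correlation, while fry called 8. In all, 1233 of 4269 genes tested (28.9%) differed between the alleles, 584 higher from BY and 649 higher from RM, and at least 2-fold 132 and 119. Without hybrid replicate 2, 693 genes differed, and by DESeq2 506.

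Genes of chromosome XIII gave more RM reads in both hybrid libraries. Of its 338 tested genes 233 were higher from RM and 12 from BY in the hybrid. Their median log2 BY over RM was −0.50 in hybrid replicate 1 and −0.51 in hybrid replicate 2, against −0.02 and −0.01 in co-culture replicates 1 and 2. From co-culture to hybrid the RM alleles rose by a median of 0.51 (95% bootstrap interval 0.49 to 0.54) and the BY alleles by 0.03 (−0.02 to 0.07). As a set the chromosome had a camera adjusted p of 2.03e-34 (adjusted p = 0.31 with an estimated correlation). The medians of the other 15 chromosomes in the hybrid lay between −0.01 and 0.07, and 0 of them passed camera. On the other chromosomes 572 genes were higher from BY and 416 from RM, and in a fit without chromosome XIII 487 and 458 were. The chromosome was singled out after its values were seen.

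**Figure D2:**
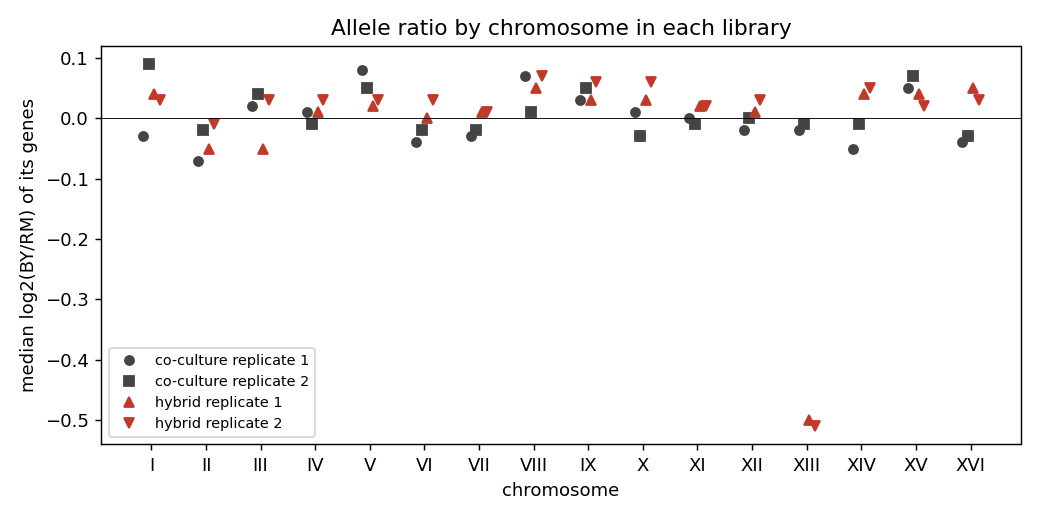
Median log2 BY over RM of the genes of each chromosome in each of the 4 libraries. Chromosome XIII lies at −0.50 and −0.51 in the hybrid libraries and at −0.02 and −0.01 in the co-culture libraries.

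The parental ratio minus the hybrid ratio asked which differences between the strains are not carried by the gene copy. A difference between RM11-1a of the co-culture and RM11-1alpha of the hybrid would also enter it. Most daughter cell genes had a higher BY over RM in the co-culture than in the hybrid. The log2 BY over RM of DSE1 was higher in the co-culture than in the hybrid by 5.20 ± 0.17, of DSE2 by 4.65 ± 0.09, of CTS1 by 4.19 ± 0.05 and of SCW11 by 3.30 ± 0.12. CTS1 went from 3.88 ± 0.09 (SD) in the co-culture to −0.30 ± 0.07 in the hybrid. Of 12 daughter cell separation genes 10 had a higher ratio in the co-culture and 0 a lower one, with a median of 1.31 and a camera adjusted p of 8.56e-25 (adjusted p = 0.215 with an estimated correlation). Most phosphate genes moved the same way. PHO84 was higher by 2.03 ± 0.05, with an overlapping non-coding RNA, VTC3 by 1.24 ± 0.06 and SPL2 by 2.70 ± 0.37. PHO84 lies on chromosome XIII, whose genes had a median difference of 0.50. Of 7 phosphate genes 6 were higher and 0 lower, with a median of 1.24 and a camera adjusted p of 1.45e-09 (adjusted p = 0.215 with an estimated correlation). In a fit without chromosome XIII 5 of 6 were higher and 0 lower, with a median of 0.96.

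Most oxidative phosphorylation genes had a lower BY over RM in the co-culture than in the hybrid. The difference was −3.32 ± 0.11 for CYC1, −2.44 ± 0.09 for RIP1, −2.00 ± 0.08 for CYT1 and −1.48 ± 0.07 for QCR2 (YPR191W), a complex III core gene. CYC1 went from −3.31 ± 0.32 (SD) in the co-culture to 0.03 ± 0.06 in the hybrid. Of 23 oxidative phosphorylation genes 22 were lower and 0 higher, with a median of −0.95 and a camera adjusted p of 4.83e-32 (adjusted p = 0.215 with an estimated correlation). Of 10 genes of the HAP1, heme and oxygen list 6 were lower and 3 higher, with a median of −0.94 and a camera adjusted p of 7.23e-06 (adjusted p = 0.215 with an estimated correlation). Of 42 mitochondrial ribosomal protein genes 17 were lower and 1 higher, with a median of −0.45 and a camera adjusted p of 0.00082 (adjusted p = 0.215 with an estimated correlation). Ergosterol genes had 15 lower and 1 higher of 18, with a median of −0.78 and a camera adjusted p of 5.87e-16 (adjusted p = 0.215 with an estimated correlation). ERG25 (YGR060W), the sterol oxidase gene, was at −1.17 ± 0.05. Iron uptake genes had 9 lower and 0 higher of 12, with a median of −0.82 and a camera adjusted p of 4.82e-08 (adjusted p = 0.215 with an estimated correlation). FRE1 (YLR214W), a metalloreductase gene, was at −1.24 ± 0.07 and FTR1 at −1.03 ± 0.06.

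Most heat shock genes and some branched-chain and cytosolic ribosomal protein genes also differed. HSP104 was higher by 0.99 ± 0.10 and STI1 (YOR027W), a co-chaperone gene, by 0.51 ± 0.05. Of 17 heat shock genes 11 were higher and 1 lower, with a median of 0.51 and a camera adjusted p of 0.00133 (adjusted p = 0.303 with an estimated correlation). BAT2 was higher by 2.28 ± 0.11, and of 11 leucine and branched-chain genes 4 were higher and 0 lower, with a median of 0.22 and a camera adjusted p of 0.00133 (adjusted p = 0.215 with an estimated correlation). Of 70 cytosolic ribosomal protein genes 30 were lower and 11 higher, with a camera adjusted p of 0.00758 towards lower (adjusted p = 0.215 with an estimated correlation). Their median was −0.08 and their mean 0.12, of opposite sign.

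The calls of 5 further lists changed when single libraries were left out. Of 17 genes of the TCA and glyoxylate cycles 9 were lower and 2 higher, with a median of −0.33 and a camera adjusted p of 0.0179 (adjusted p = 0.264 with an estimated correlation). SDH1 (YKL148C), a succinate dehydrogenase gene, was at −1.41 ± 0.16. The adjusted p of that list was 0.0588, 0.0797, 0.0947 and 0.067 without hybrid replicate 1, hybrid replicate 2, co-culture replicate 1 and co-culture replicate 2, and its range over 7 alternatives was 0.014 to 0.264. Of 26 proteasome genes 8 were higher and 0 lower, with a median of 0.13 and a camera adjusted p of 0.0188 (adjusted p = 0.264 with an estimated correlation). PRE7 was higher by 0.67 ± 0.09. Without the same libraries in the same order its adjusted p was 0.0929, 0.0543, 0.0907 and 0.0733, in a range of 0.0103 to 0.264. Of 50 ribosome biogenesis genes 13 were lower and 4 higher, with a median of −0.15 and a camera adjusted p of 0.0381 (adjusted p = 0.407 with an estimated correlation). NOP1 (YDL014W), the fibrillarin gene, was at −0.62 ± 0.07. Without the same libraries its adjusted p was 0.0711, 0.22, 0.127 and 0.13, in a range of 0.0314 to 0.407. Of 5 histidine genes 3 were higher and 0 lower, with a median of 0.31 and a camera adjusted p of 0.0181 (adjusted p = 0.407 with an estimated correlation). HIS4 (YCL030C), a histidine synthesis gene, was higher by 0.86 ± 0.14. Without hybrid replicate 1, co-culture replicate 1 and co-culture replicate 2 its adjusted p was 0.12, 0.0643 and 0.0952, in a range of 0.014 to 0.407. Of 5 lysine genes 2 were lower and 0 higher, with a camera adjusted p of 0.0716 towards lower. Their median was 0.12 and their mean −2.57, of opposite sign. That mean rests on LYS2, which had a fitted value of −12.99 and 0 RM reads in the hybrid. The list passed camera when any 1 library was left out. A test without LYS2 was not run, so this does not show a change of the other lysine genes.

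**Figure D3:**
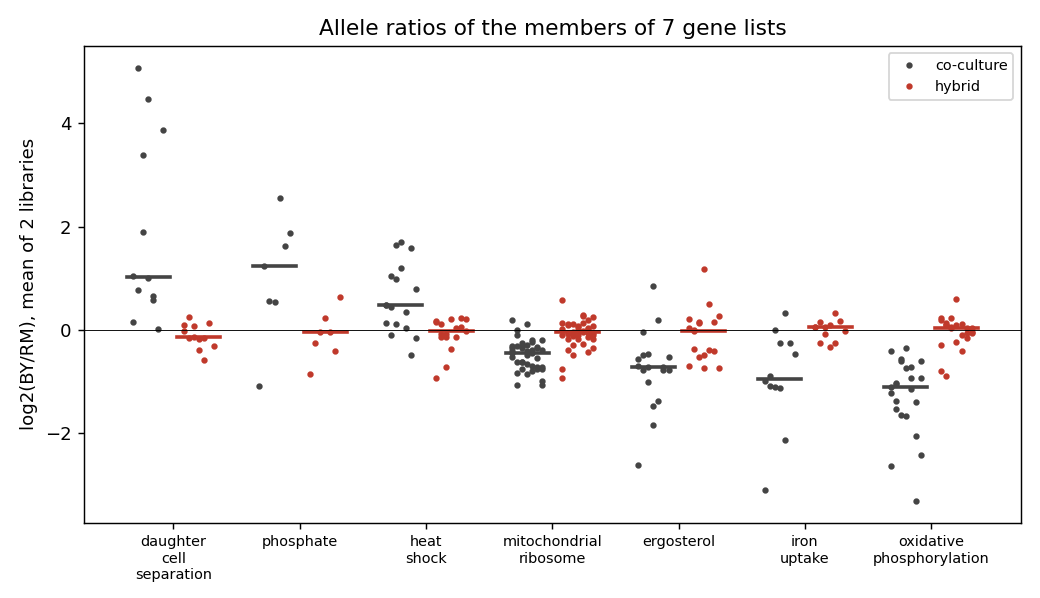
Log2 BY over RM of each member of 7 gene lists, averaged over the 2 co-culture libraries and over the 2 hybrid libraries, with the median of each list. The oxidative phosphorylation median is −1.12 by the fit in the co-culture and 0.03 in the hybrid.

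Some genes outside those lists changed allele balance between the cultures. OLE1 (YGL055W), the fatty acid desaturase gene, had a log2 BY over RM of −1.06 ± 0.03 (SD) in the co-culture and 1.47 ± 0.07 in the hybrid, a difference of −2.53 ± 0.05. QDR2 (YIL121W), a drug exporter gene, had a difference of 2.65 ± 0.14. In all, 1178 of 4269 genes tested (27.6%) had a ratio that differed between co-culture and hybrid, 566 higher and 612 lower in the co-culture, and at least 2-fold 141 and 75. With column totals only the split was 734 and 448, and with shared library totals 722 and 456. Chromosome XIII held 176 of the higher and 8 of the lower genes, which leaves 390 higher and 604 lower on the others, and in a fit without it 404 were higher and 542 lower. Without hybrid replicate 2, co-culture replicate 1 and co-culture replicate 2 the counts were 711, 776 and 734, and DESeq2 called 352. Adjusted over the list alone, the counts of called lists were the same except for leucine (5 higher), cytosolic ribosomal proteins (13 higher), ribosome biogenesis (14 lower) and oxidative phosphorylation (23 lower). Of 29 lists 14 passed camera (15 at an unadjusted p), and with an estimated correlation 0 passed, while 5 did at an unadjusted p and fry called 17.

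Crossing the calls sorted the genes by which of the 3 tests called them. CTS1, CYC1, RIP1 and PHO8 (YDR481C), the vacuolar phosphatase gene, are examples of large parental differences with a trans part, and CTR3, ARG4 and RPN4 of large allele differences within the hybrid. Of 4269 genes, 497 (11.6%) were cis only, called between the parents and between the alleles but not in the difference of ratios. Another 597 (14.0%) were trans only, called between the parents and in the difference but not between the alleles. A missed test does not show that a part is absent. In simulated data a 1.5-fold difference was called in 50.7% of altered genes for the difference of ratios. For the hybrid ratio it was called in 77.6%. Both parts were called in the same direction in 115 (2.7%) and in opposite directions in 205 (4.8%). In 220 (5.2%) both parts were called without a parental difference, named compensatory here. LYS2 fell in this class, but its RM copy was without reads in the hybrid only, and the named RM parents differ. Its call therefore does not show cis and trans regulation that offset each other. No comparison was called in 1934 (45.3%), and 701 (16.4%) had another mixture of calls. Chromosome XIII held 99 compensatory, 51 opposite, 41 cis only, 16 trans only and 11 same-direction genes. The cis and trans parts share the hybrid libraries, so an error there moves them in opposite directions. Calls with opposite signs numbered 425 against 169.8 for independent lists, and calls with the same sign 115 against 170.5. Off chromosome XIII these were 275 against 129.2 and 104 against 120.7. In 20 simulated data sets without differences, 0 compensatory and 0 opposite genes were called at most. The simulated sets leave out the real effects and the independent lists leave out the shared libraries, so neither shows how much of the excess a shared error makes. Without hybrid replicate 1, hybrid replicate 2, co-culture replicate 1 and co-culture replicate 2 in turn, same-direction genes numbered 59, 46, 76 and 75, and opposite genes 122, 93, 122 and 109. Without co-culture replicates 1 and 2 trans-only genes numbered 385 and 355, and without hybrid replicate 2 compensatory genes numbered 132. DESeq2 gave 263 cis-only and 202 trans-only genes.

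**Figure D4:**
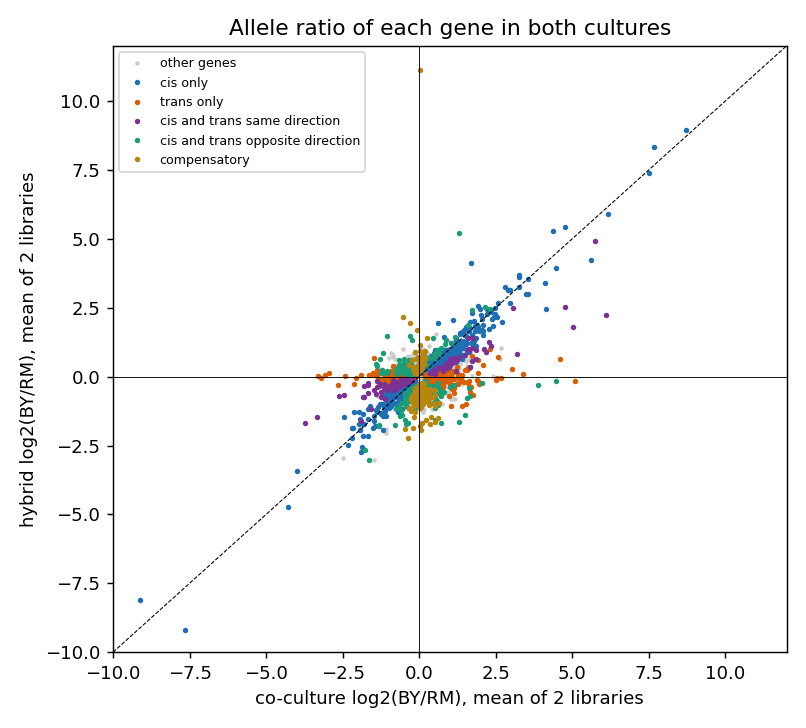
Mean log2 BY over RM of each gene in the 2 co-culture libraries against that in the 2 hybrid libraries, with a pseudocount of 0.5 reads and coloured by regulatory class. LYS2 lies at 11.11 in the hybrid, a value that rests on 0 RM reads there.

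Inheritance compared the hybrid total of each gene with each parent in the co-culture. The RM strain there was RM11-1a, while the RM parent of the hybrid was RM11-1alpha. Many mating genes lay below both parents, with STE2 at 33.0 CPM in the hybrid against 3233.2 in BY and 5113.7 in RM, log2 differences of −6.62 and −7.28. All 5 a-specific and all 9 haploid-specific genes were below both. Of 13 pheromone response genes 6 were below both and 5 differed from neither parent. Of 2 alpha-specific genes 1 was below both and 1 differed from neither. ZRT1 lay above both, at 518.2 against 267.0 and 268.8, log2 differences of 0.95 and 0.95. Of 50 ribosome biogenesis genes 31 lay above both parents and 0 below both. Of 23 oxidative phosphorylation genes 14 lay between the parents and 5 differed from BY only, and of 42 mitochondrial ribosomal protein genes 29 differed from BY only. Of 12 daughter cell separation genes 7 lay between the parents.

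Of 4267 genes, 330 (7.7%) lay above both parents, 291 (6.8%) below both and 275 (6.4%) between them. The hybrid differed from BY only in 980 (23.0%) and from RM only in 468, and 1923 (45.1%) differed from neither. Above both, 102 of the 330 genes lay on chromosome XIII. The hybrid total enters both tests, so genes above and below both parents can be called together through a shared error. Independent lists would give 159.3 above and 140.8 below both. In 20 simulated data sets without differences 0 such genes were called. The correlation of the 2 log2 differences was 0.30 there, as in the data. Their covariance was 0.008, against 0.124 in the data, where real effects are present. The simulated sets leave out real effects and the independent lists leave out the shared libraries. Neither shows how much of the excess a shared error makes. Without co-culture replicate 2, 206 genes lay above both, and DESeq2 placed 154 above and 178 below both.

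Among cis-only, trans-only, same-direction and opposite genes, more than 50% of each class lay nearer RM in the hybrid. The position was not measured in the other classes. CLN3 (YAL040C), a G1 cyclin gene, stood at 440.4 CPM in the hybrid, 225.8 in BY and 450.9 in RM, and MRPS9 (YBR146W), a mitochondrial ribosomal protein gene, at 324.4, 200.5 and 342.6. On a scale from 0 at the RM level to 1 at the BY level, the hybrid had a median position of 0.25 in 597 trans-only genes (95% bootstrap interval 0.19 to 0.30) and of 0.45 in 495 cis-only genes (0.42 to 0.48). Of the trans-only genes 393 (65.8%) were nearer RM, and so were 58.0% of cis-only, 60.5% of opposite and 73.0% of same-direction genes. Opposite genes higher in BY had a median position of 0.50 and those higher in RM one of 0.24. Chromosome XIII held 51 of the 205 opposite genes. Trans-only genes numbered 272 among those that differed from BY only and 113 among those that differed from RM only.

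The sizes of cis and trans differences were compared across genes, which are not independent replicates. The median absolute log2 difference was 0.17 in cis and 0.27 in trans, against 0.16 between the hybrid libraries and 0.17 between the co-culture libraries. The trans value carries the error of both cultures and the cis value that of the hybrid alone, so these medians do not show that trans differences are larger. Variances across genes were estimated as covariances between replicates 1 and 2, which leaves out error that the replicates do not share. The variances were 0.51 for the parental ratio, 0.40 for cis and 0.27 for trans. Without 20 genes at 8-fold or more in both cultures they were 0.37, 0.25 and 0.28. LYS2, which had 0 RM reads in the hybrid, and chromosome XIII were kept in all of these variances. With cis from hybrid replicate 1 and trans from hybrid replicate 2, the correlation across 4269 genes was −0.20 (Spearman −0.15). On the 15 chromosomes other than XIII it was −0.17 (Spearman −0.07). With all chromosomes but without the strain marker genes, LYS2 among them, it was −0.15 (Spearman −0.15). The parental ratio and the hybrid ratio had a Pearson correlation of 0.65 and a Spearman correlation of 0.37 across genes.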

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

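The tests on chromosome XIII, on a scaling factor and without one-sided genes were chosen only after the result was seen, as was the use of the planned correlation from separate hybrid libraries as a test of counting error. The genes and lists named first differed between the co-culture and the hybrid by a test of the difference itself, and the nearness to RM and the correlation weighed at the end are values without such a test.

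Daughter cell genes led the genes whose log2 BY over RM was higher in the co-culture than in the hybrid. The difference was 5.20 for DSE1, 4.65 for DSE2, 4.19 for CTS1 and 3.30 for SCW11. It was 2.70 for SPL2 and 2.65 for QDR2. NDJ1, a meiotic gene, had 3.27, and without hybrid replicate 2 it had 2.97 with an adjusted p of 0.082, the highest of its alternatives, which started at 9.29e-06. The value for IME1, 4.30, is a fitted value that depends on the prior count and is no bound, since IME1 had 2 RM reads in the co-culture. In the other direction CYC1 had −3.32, RIP1 −2.44, HMX1 −3.16 and OLE1 −2.53. FRE4 (YNR060W), a metalloreductase gene, had −3.10, ULI1 (YFR026C), a gene of the unfolded protein response, −2.73 and YHR033W, of unknown function, −3.96. The value for LYS2, −12.99, is also a fitted value that depends on the prior count, since LYS2 had 0 RM reads in the hybrid.

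Gene lists differed in their median as well. The median difference of log2 BY over RM was 1.31 for daughter cell separation, 1.24 for phosphate, 0.51 for heat shock, 0.31 for histidine, 0.22 for leucine and branched-chain synthesis and 0.13 for the proteasome. It was −0.95 for oxidative phosphorylation, −0.94 for the HAP1, heme and oxygen list, −0.82 for iron uptake and −0.78 for ergosterol. It was −0.45 for mitochondrial ribosomal proteins, −0.33 for the TCA and glyoxylate cycles, −0.15 for ribosome biogenesis and −0.08 for cytosolic ribosomal proteins. With an estimated correlation, adjusted p-values of these 14 lists lay between 0.215 and 0.407, so by camera they passed only at the preset correlation. By fry, which does not compare a list with other genes, 13 of the 14 passed, and ribosome biogenesis did not (adjusted p = 0.0549). In all, 1178 genes differed, and the genes of chromosome XIII had a median difference of 0.50.

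Genes of chromosome XIII had more RM reads in the hybrid. Read assignment that favours RM on this chromosome was excluded, since the co-culture median of the same genes was −0.02 or higher in both libraries. Loss of BY copies was excluded, since the BY alleles changed by 0.03 (95% bootstrap interval −0.02 to 0.07). Extra RM copies of the chromosome in hybrid cells may be the source, since the RM alleles rose by 0.51 (0.49 to 0.54), a ratio of 1.42. That is below the 2-fold rise of 1 extra RM copy in every cell, if RNA follows copy number. The values argue against that form of the explanation. The RM rise ran along the whole chromosome, with a median between 0.43 and 0.59 in each of 12 windows. Other forms of it stay open. The BY alleles also stayed within 0.1 in only 7 of 12 windows, under the 10 set in the test. The BY medians of the windows lay between −0.12 and 0.19, and no DNA was measured. An RM variant of this chromosome in the hybrid's own RM parent was not tested and stays open.

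The trans-only genes had a hybrid level nearer RM (65.8% of them), which is no trait of theirs alone, since 58.0% of cis-only, 60.5% of opposite and 73.0% of same-direction genes were nearer RM too. A single scaling factor was excluded, since it would move genes higher in BY and genes higher in RM to opposite sides of 0.5, and both lay below it, at 0.21 (0.13 to 0.30) and 0.29 (0.19 to 0.37). The gene lists as the whole source were excluded, since the genes outside them had a median of 0.24 (0.18 to 0.31), and so was chromosome XIII, since the genes of the other 15 chromosomes had 0.24 (0.18 to 0.29). These intervals treat genes as independent, which genes that share a regulator are not. RM alleles that act over BY alleles on shared regulators may be the source, and this was not tested, nor were the change from haploid to diploid cells and the different RM parent, which all stay open.

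Genes with a cis difference tended to have a trans difference of opposite sign. Counting error shared through the hybrid libraries was excluded as the whole source, since the correlation across genes was −0.20 (−0.32 to −0.10) with cis and trans from separate hybrid libraries. How much of it rests on chromosome XIII and on genes read almost wholly from 1 strain stays open: without them and without the markers the correlation was −0.10 (−0.16 to −0.04) in 3911 genes, with a Spearman value of −0.07. Errors common to both hybrid libraries but absent from the co-culture would enter both parts and were not tested. A bias in reads assigned to an allele that is alike in both cultures would enter cis only, since it cancels from trans. Selection that keeps expression levels alike might also give this sign and was not tested.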

How the results depend on the processing

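Fits without chromosome XIII, without genes at 8-fold or more in both cultures and without the strain markers were chosen after the data were seen, and the other tests were planned. Of the named gene results, 394 kept their direction and side of the threshold with RLE scaling, 394 with no filter and 327 with DESeq2, where 65 no longer passed. The cause of the changes was not tested unless stated. With DESeq2 the totals gave 809 genes, the co-culture ratio 834, the hybrid ratio 506 and the difference of ratios 352. DESeq2 gave 263 cis-only, 202 trans-only, 27 same-direction, 39 opposite and 72 compensatory genes. It placed 154 genes above both parents, 178 below both, 169 between them and 286 as differing from RM only. A minimum log2 change of 0.32 left 1020 genes in totals, 52 same-direction and 79 opposite genes and 196 above both parents, since it adds a condition. Without the library block 62 genes were same-direction and 102 opposite. Without chromosome XIII 132 were opposite and 109 compensatory, against 154 and 121 off that chromosome when all genes were fitted, and the cause of that further change was not tested. With an estimated correlation 0 lists passed in totals, 0 in the co-culture ratio and 0 in the difference of ratios, and fry called 26, 23 and, in the hybrid ratio, 8. With cis and trans from the same libraries their correlation was −0.30, since they then share an error, and over the other alternatives that change 1 choice it lay between −0.27 and −0.15. With chromosome XIII, the markers and one-sided genes all left out it was −0.10. Against the mid-parent the direction of DSE1 (0.84), CTS1 (0.58) and MET17 (4.47) in totals was reversed. That mid-parent is a mean of log2 levels, which lies far below the mean of the levels where 1 parent has few reads.

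With 1 library left out, the lone library of its group was taken to vary like the others. The count then ranged from 1199 to 1273 for totals, 1178 to 1789 for the co-culture ratio, 693 to 1138 for the hybrid ratio and 711 to 872 for the difference of ratios. It ranged from 350 to 439 for cis only, 355 to 498 for trans only, 46 to 76 for same direction, 93 to 122 for opposite and 132 to 176 for compensatory. It ranged from 206 to 270 for above both parents, 223 to 248 for below both and 194 to 222 for between them. Fewer samples leave fewer degrees of freedom for the spread. Depth limits genes with few reads, since 3 reads correspond to 0.72 to 1.11 CPM.

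The library numbers were not taken as pairs. Deviations of libraries with the same number had a correlation of 0.36 across 3352 genes, which rests on 2 numbers. With the replicate number as a block, totals gave 2003 genes (1001 higher, 1002 lower), the co-culture ratio 1890, the hybrid ratio 1231 and the difference of ratios 1172. Under that block 1 list, lysine, passed in the hybrid ratio (adjusted p = 0.00187). It holds LYS2, which had 0 RM reads in the hybrid. The cytosolic ribosomal protein list no longer passed in totals (0.0503), and 3 lists passed there in its place, oxidative phosphorylation (0.0156), histones (0.0156) and the HAP1, heme and oxygen list (0.00419).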

Other observations

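The fit without chromosome XIII and the set of genes at 8-fold or more in both cultures were chosen after the result was seen, and the other tests in this part were planned. Cell cycle genes differed between hybrid and co-culture totals without passing as a list. CLN2 (YPL256C), a G1 cyclin gene, fell by 0.89 ± 0.09, CLB1 (YGR108W), a mitotic cyclin gene, fell by 0.56 ± 0.11, and CLN3 rose by 0.39 ± 0.06. Of 10 genes of the G1 to S cyclin list 7 fell and 1 rose (the same adjusted over the list alone), with a camera adjusted p of 0.118. Of 5 histone genes 4 fell and 0 rose (adjusted p = 0.146), with HHF1 (YBR009C), a histone H4 gene, at −0.49 ± 0.06. Sulfur genes moved both ways, 6 higher and 7 lower of 19 (8 lower adjusted over the list alone, camera adjusted p = 0.649). MET6 (YER091C), the methionine synthase gene, fell by 1.11 ± 0.11, while CYS3 (YAL012W), a cysteine synthesis gene, rose by 0.40 ± 0.06.

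Further lists did not pass in totals. Respiration genes had 11 higher and 2 lower of 23 in the hybrid (adjusted p = 0.0697), and the list passed without hybrid replicate 1 (0.0458), without hybrid replicate 2 (0.0388) and without chromosome XIII (0.0444), in a range of 0.00892 to 0.379 over the 7 alternatives that keep all chromosomes. Iron genes had 0 higher and 4 lower of 12 (0.118), with FRE2 at −1.17 ± 0.11, and passed without hybrid replicate 1 (0.0398), in a range of 0.0315 to 0.394. The other adjusted p-values were 0.0728 for the HAP1, heme and oxygen list, 0.147 for zinc, 0.29 for histidine, 0.309 for hexose transport, 0.384 for pyrimidine, 0.446 for arginine, 0.571 for lysine, 0.673 for nitrogen catabolism, 0.735 for the TCA cycle, 0.735 for the proteasome and 0.987 for glycolysis. In the co-culture ratio the haploid-specific list missed the threshold (0.0527), with 2 genes higher in BY and 5 in RM of 9, and passed without co-culture replicate 1 (0.0277), in a range of 0.0277 to 0.503.

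Some genes were read almost wholly from 1 strain in both cultures. At 8-fold or more in both cultures were 20 genes, all 20 with the same sign, 16 higher in BY and 4 higher in RM. Of these 1, RPL14B, had a ratio that differed between co-culture and hybrid (adjusted p = 9.38e-06), at 5.74 ± 0.16 (SD) and 4.92 ± 0.34. A bias in reads assigned to an allele would also give a ratio alike in both cultures. It was not tested for these genes. DNF2 had 499 BY reads and 0 RM reads in the hybrid, at least 169-fold higher in BY, and its adjusted p by DESeq2 was 0.0765.

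Read counts varied more between libraries of a group than counting error gives, and less than between groups. The chi-square per degree of freedom between the 2 libraries of a group was 1.94 for BY and 1.99 for RM reads in the hybrid, and 1.86 and 2.06 in the co-culture. Between libraries of different groups it lay between 14.09 and 22.02. The variance of allele shares between libraries of a group was 1.10 times the binomial one in the hybrid and 1.14 times in the co-culture.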
